A study of Drosophila melanogaster with 2 samples.

How the data were processed

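Total RNA was extracted with Trizol from whole larvae and sequenced by Illumina for non-coding RNA profiling, per the labels' protocols. Bowtie (version not given in the sources used here) and the genome build dm3 are named in the submitters' processing notes. The adapter trimming, any length filter, the microRNA annotation release and the treatment of reads that match several hairpins are not given in the sources used here. The deposited table holds whole-number read counts per microRNA product for 1 wild-type and 1 cdk9-G57S library, and a footer calls their totals raw microRNA reads. The totals in the footer equalled the sums of the 101 listed products (2135660 and 2204104 reads), so they cover listed products alone. No listed product had fewer than 1023 reads summed over both libraries. Products below that level, and the number of reads sequenced, were not analysed here. The footer lines (totals, their difference and the percent difference) are not products and were left out. The same table holds a second pair of columns, a normalized signal that the authors made by dividing each library's counts by 1 size factor, per the file headers with DESeq2. The factors recovered from the values were 0.907 for wild type and 1.10 for cdk9-G57S. The header describes this as normalization by library size, while the raw totals differed by 3.15% of their mean and the normalized total was 15.2% lower in cdk9-G57S.

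Each product is identified by an accession of a hairpin and a suffix of 1 or 2. None of the 83 hairpin accessions could be paired with a name in the gene tables at hand (0 matched), and the table gives no names or positions. The microRNA lists, genomic clusters, the search for UGU at the apical junction and the split of intronic from intergenic hairpins that were planned before the data were examined therefore could not be computed. The annotation at hand was BDGP6.54, not dm3, so no coordinate is given; it holds 262 microRNA hairpins. The suffix was not read as a 5p or 3p arm, because a product with suffix 1 and one with suffix 2 from different hairpins held nearly the same reads (67924 and 67925 in wild type).

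The raw counts were used for every comparison. With 1 library per genotype, no test between genotypes was run, and the G57S label could not be checked against expression. Each count was divided by its library total. The ratio of shares (cdk9-G57S over wild type) was given an exact conditional-binomial 95% interval, and shares were given exact Clopper-Pearson 95% intervals. Differences of log2 ratios within a hairpin were given normal-approximation intervals from the 4 counts. These intervals cover counting error only. A size rule fixed before the data were examined took the place of a test: a ratio of at least 2 or at most 0.5 with an interval that excluded 1, for products with at least 20 reads summed, a minimum that removed none. The rule for naming, also fixed then, would have named the 10 most abundant products and the 10 largest increases and decreases; because identifiers carry no names, it was shortened to the 2 largest increases and the 2 largest decreases. Within-hairpin differences were compared with 10000 draws of random pairs from different hairpins, matched on mean share in 5 bins.

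The alternatives were DESeq2's median-of-ratios factors, edgeR's TMM factors, a total without the most abundant product, other minimums, a pseudocount of 5, limits of 1.5-fold and 4-fold, and reads summed per hairpin. Alternatives chosen after the data were seen kept 1 product of each set with near-identical reads, or used subsets of hairpins. Near-identical means from different hairpins with reads that differed by at most 2% in both libraries. There were 4 such sets with 9 products, including 1 pair with exactly equal reads in both libraries. When ratios were reassigned among products 1000 times, a median of 0 and at most 4 near-identical pairs arose, against 6 observed. The largest set held 3 products, so the 6 pairs are not independent. If they are the same reads counted for each copy, 6.17% of wild-type and 6.52% of cdk9-G57S reads were counted again.

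The ratio rule was tested on simulated Poisson counts for the 101 products in 100 runs. It called 100% of the products simulated as 4-fold higher and 100% of those simulated as 4-fold lower, and 0% of unchanged products; 95.2% of the intervals of unchanged products held the true ratio. In simulated hairpins with a shared ratio, the within-hairpin difference lay at percentile 0 of random pairs in each of 20 runs. Without a shared ratio the percentile ran from 1.8 to 93.4 over 20 runs, with a median of 41.2. The shared ratio was simulated with little noise between the products, so partial sharing was not tested. The simulations held no variation between samples, so they say nothing about replicate error. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors alone.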

Results

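High-throughput sequencing of non-coding RNA was used to measure microRNAs in whole Drosophila melanogaster larvae aged 48 h and grown at 25 °C. Wild-type larvae were compared with larvae homozygous for cdk9-G57S, a mutant allele of the gene for Cdk9. Cdk9 is the kinase of the elongation factor P-TEFb, which phosphorylates the C-terminal domain of RNA polymerase II. The question, as far as the series title states it, concerned whether the Microprocessor (the Drosha and Pasha complex that cuts microRNA hairpins from their primary transcripts) must be recruited to elongating polymerase for microRNAs to be differentially expressed. There was 1 library per genotype, so no difference between the genotypes has a replicate check, and no p-value is given. All intervals are 95% intervals of counting error alone, and reads copied by PCR are not independent molecules, so the true uncertainty is wider. The table counted microRNAs and not messenger RNAs, so the cdk9 transcript itself could not be used to check the genotype labels.

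The table listed 101 microRNA products from 83 hairpins. Of these hairpins, 18 had 2 listed products and 65 had 1. The wild-type library held 2135660 reads over these products and the cdk9-G57S library held 2204104, which is 3.20% more. Every listed product was detected in both libraries, with at least 251 reads in wild type and 134 in cdk9-G57S. The least abundant product had 1023 reads summed over both libraries. At this depth a product's share of the library was measured with a narrow counting interval, and the counting error of a log2 ratio averaged 0.05 (root mean square over the products). Products were identified by hairpin accession, without microRNA names or genome positions. They are therefore described below by abundance rank, and only the 2 largest increases and the 2 largest decreases are given by identifier.

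The first comparison asked how the microRNA pool was divided among products in each genotype. A single product was the most abundant in both libraries, and its share was 2.14-fold lower in the mutant, at 35.1% of wild-type reads (95% exact Clopper-Pearson interval 35.0 to 35.2) and 16.4% of cdk9-G57S reads (16.3 to 16.4). The second product by mean share went the other way, from 5.14% in wild type to 16.0% in cdk9-G57S, a 3.11-fold higher share. The third product had 4.34% and 14.1% of the reads, a 3.26-fold higher share in the mutant. The fourth product had 10.6% in wild type and 5.84% in cdk9-G57S, while the fifth was at 3.24% and 3.10%. The 3 most abundant products of each library together took 50.9% of the wild-type reads and 46.5% of the cdk9-G57S reads, and the top 10 took 70.4% and 65.7%. In all, 36.3% of the reads would have to be reassigned between products to turn one library's composition into the other's.

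**Figure D1:**
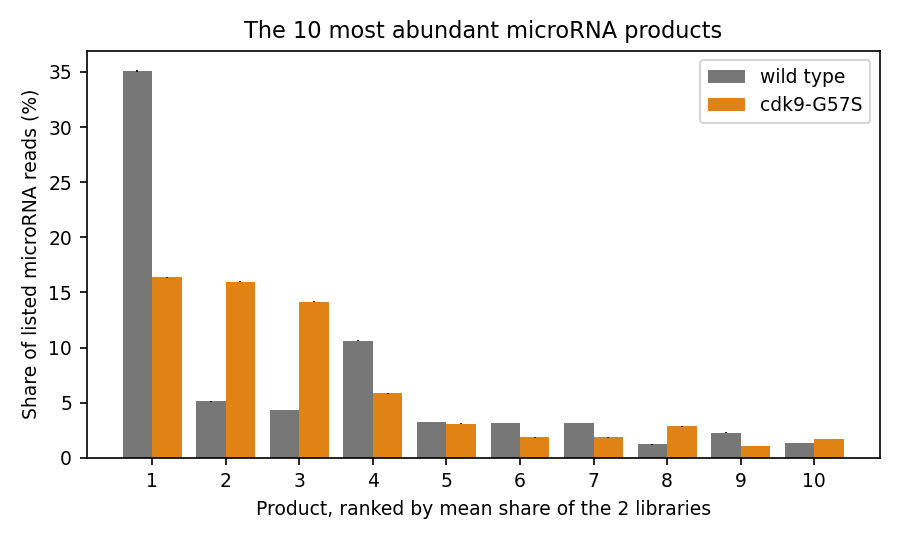
Share of the listed microRNA reads (%, vertical axis) taken by each of the 10 most abundant products, ranked by their mean share over the 2 libraries (horizontal axis). Grey bars are wild type, orange bars are cdk9-G57S, and error bars are exact 95% counting intervals. The first product stood at 35.1% in wild type and 16.4% in cdk9-G57S, whereas the second and the third were higher in cdk9-G57S, at 16.0% and 14.1%. The sixth and seventh products held near-identical reads and may be the same reads counted for 2 hairpins.

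The second comparison asked which products differed in relative abundance between the genotypes. With each library scaled to its total, 28 of the 101 products had at least a 2-fold higher share in cdk9-G57S and 17 had at least a 2-fold lower share, all with a counting interval that excluded a ratio of 1. The remaining 56 lay within 2-fold. The 28 higher products together accounted for 15.3% of wild-type reads and 48.4% of cdk9-G57S reads. The 17 lower products accounted for 45.7% and 20.2%. Log2 ratios (cdk9-G57S over wild type) ran from -3.18 to 4.28, with a median of 0.24, quartiles of -0.74 and 1.22 and an SD of 1.42 over products. The counting interval excluded a ratio of 1 for 99 products, which compares these 2 libraries and not the genotypes.

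The largest increase was that of the product MI0000432_1, which moved in rank from 96 to 33 among the 101 products. It had 504 reads in wild type and 10094 in cdk9-G57S, a 19.4-fold higher share (interval 17.7 to 21.3). The product MI0005808_1 had 1089 and 17118 reads, a 15.2-fold higher share (14.3 to 16.2). The largest decrease was that of MI0005869_1, with 1173 reads in wild type and 134 in cdk9-G57S, a 9.03-fold lower share (7.55 to 10.9) that made it the least abundant listed product of the mutant library. The product MI0000356_2 was next, with 18435 and 2993 reads, a 6.36-fold lower share (6.12 to 6.61). The other listed product of this last hairpin was also lower, by 4.48-fold. At a 4-fold limit, 8 products were higher and 6 were lower. The product MI0005869_1 ranked 97 of 101 by mean share, near the lowest summed reads of any listed product (1023). If products were listed by summed reads, one near that level with few reads in 1 library needed many in the other. Such a cut would favour large ratios among the least abundant listed products.

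The balance between higher and lower products depended on the scaling. The authors' deposited values were divided by size factors of 0.907 for wild type and 1.10 for cdk9-G57S, which lowers each log2 ratio by 0.24 relative to scaling by total reads. On that scale 24 products were at least 2-fold higher and 24 were at least 2-fold lower. Thus 50.0% of the 2-fold differences were increases, compared with 62.2% under scaling by total. The median log2 ratio is 0 by construction on the deposited scale, so part of this evenness follows from the scaling. With the most abundant product left out of both totals the balance turned, with 23 products at least 2-fold higher, 29 at least 2-fold lower and a median log2 ratio of -0.13. All 24 higher products of the deposited scale were among the 28, and all 17 lower products were among the 24. This overlap had to arise, because the change of scale shifts all log2 ratios by the same amount. Among the 10 most abundant products, 3 were at least 2-fold higher, 2 were lower and 5 lay within 2-fold under scaling by total. The deposited scale gave 2 higher, 5 lower and 3 within 2-fold. Of these 5 lower products, 2 held near-identical reads, with 67925 and 67924 in wild type and 40964 and 40961 in cdk9-G57S. They were the sixth and seventh by mean share, and lay within 2-fold under scaling by total. They may be the same reads counted for 2 hairpins, so the 5 need not be separate microRNAs.

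**Figure D2:**
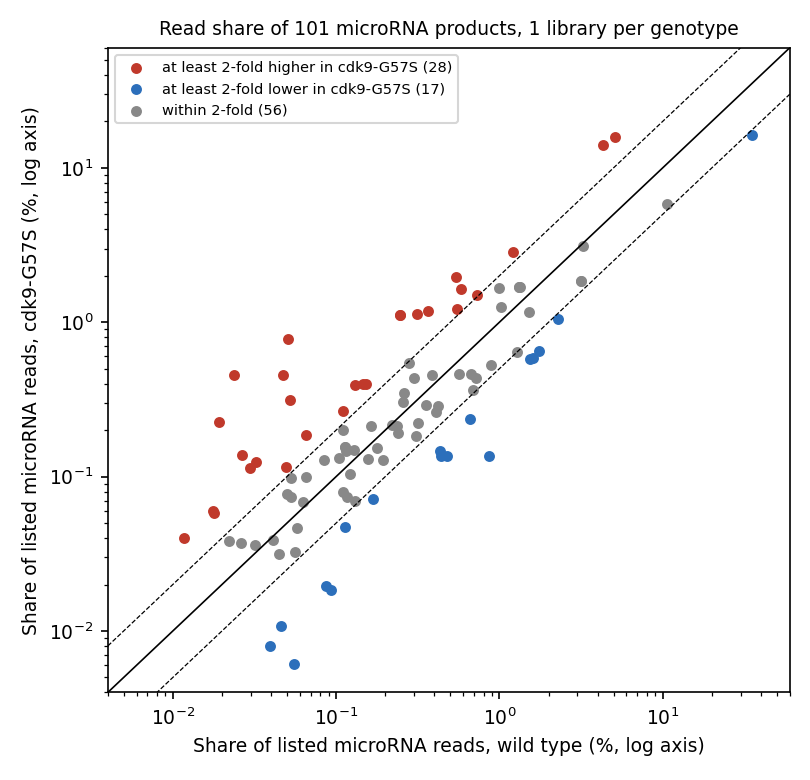
Share of listed microRNA reads in wild type (%, horizontal log axis) against cdk9-G57S (%, vertical log axis), with 1 point for each of 101 products. The solid line marks equal shares and the dashed lines mark 2-fold differences. The 28 red points are at least 2-fold higher in cdk9-G57S, the 17 blue points at least 2-fold lower, and the 56 grey points within 2-fold.

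The third comparison was made within hairpins. As background, a hairpin is cut out by the Microprocessor and then by Dicer, which leaves its arms as a duplex. The change in the ratio of one product to another does not depend on how the libraries are scaled, since each library's factor cancels. In all 18 hairpins with 2 listed products, the ratio between the products differed between the libraries by more than counting error. The products' log2 ratios lay a median of 1.73 apart, and 12 of the 18 hairpins had products at least 2-fold apart. Whether the more or the less abundant product had the lower ratio depended on the ranking: in these 12 hairpins it was the less abundant product in 6 and the more abundant in 6 when products were ranked by their wild-type reads, but 9 and 3 when ranked by their cdk9-G57S reads. Random pairs of products from different hairpins, matched on abundance, lay a median of 1.33 apart, with 95% of 10000 draws between 0.74 and 2.09. Products of 1 hairpin were thus no closer to each other than products of different hairpins. The random pairs could include near-identical products, which lie close together, so not all of them need be unrelated.

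In 9 hairpins one product had a higher share in cdk9-G57S and the other a lower share, and 8 of these 9 did so under all 4 scalings tried. In 3 of them both products passed the 2-fold limit in opposite directions under scaling by total. The widest separation was 50.2-fold. There, one product had an 11.8-fold higher share in cdk9-G57S, from 410 reads in wild type to 4973. Its partner had a 4.27-fold lower share, from 977 reads to 236. The partner went from 70.4% of the hairpin's reads in wild type (68.0 to 72.8) to 4.53% in cdk9-G57S. It ranked 99 of 101 by mean share, so the doubt about listing by summed reads given for MI0005869_1 applies to it too. The second widest involved the hairpin of the second most abundant product, whose share was 3.11-fold higher while that of its rare partner was 5.05-fold lower, from 1991 reads to 407. In the opposite sense, one hairpin's less abundant product went from 14.4% to 38.9% of its hairpin's reads, with its partner nearly level at a ratio of 0.956. The more abundant of the 2 products was not the same one in both libraries for 4 hairpins. In 3 of the 18 hairpins a product's reads differed by at most 2% from those of another hairpin's product in both libraries, so reads from copies may have been counted for both and these hairpins' ratios are uncertain. At a limit of 10% the number was 10 of the 18, and the same doubt may hold for them. Ratios were not reassigned at this wider limit, which allows more accidental matches, so some of the 10 may be accidental. These 10 included the hairpin of the second most abundant product and 2 of the 4 in which the more abundant product changed.

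**Figure D3:**
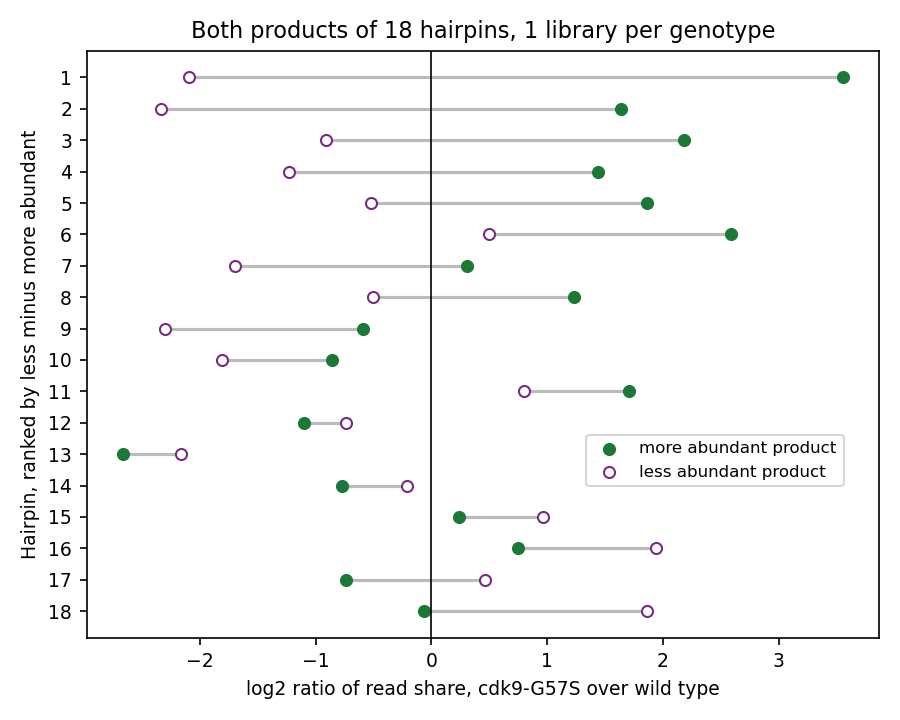
Log2 ratio of read share, cdk9-G57S over wild type (horizontal axis), for both products of the 18 hairpins that had 2 listed products, ranked by the difference between the products (vertical axis). Filled green points are the more abundant product by mean share over both libraries, open purple points the less abundant one, and grey lines join products of 1 hairpin. Products lay a median of 1.73 log2 units apart, and 9 lines cross 0.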

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

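Scaling moved the balance of higher and lower products. It shifts all log2 ratios alike, by at most -0.37, so the 4 named products, chosen as the most extreme, could not leave the 2-fold limit; the product MI0000432_1, for example, lay between 3.91 and 4.28. Under median-of-ratios scaling the median log2 ratio was 0.00 by construction, and under TMM it was 0.0687. With the most abundant product left out of the totals it was -0.13, with 29 products at least 2-fold lower and 23 higher. With reads summed per hairpin it was 0.36, with 10 hairpins lower and 24 higher, out of fewer features. A limit of 1.5-fold gave 66 products, 36 higher and 30 lower, and a limit of 4-fold gave 14 in all, 8 higher and 6 lower; both follow from the limit itself. No minimum, and a minimum of 100 reads summed, removed no product and so tested nothing. A pseudocount of 5 left the 2-fold counts at 28 and 17. The next settings were chosen after the data were seen. Keeping 1 product per near-identical set gave 27 higher and 17 lower of 96 products, and it raised the share of the most abundant product to 37.4% in wild type and 17.5% in cdk9-G57S and that of the top 10 to 73.3% and 70.1%. The median difference within hairpins was 1.83 over the 8 hairpins with no product within 10% of another hairpin's reads, and 1.47 over the 10 hairpins with at least 1000 reads of each product in each library. The planned comparisons of microRNA lists, apical UGU motifs and intronic hairpins were not run, for want of names and positions. No paired analysis was possible because each genotype had 1 library. The counting intervals are narrow, but they leave out variation between samples, PCR copies and reads counted for several hairpins.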

Other observations

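The comparison of products within hairpins against random pairs and the need for replicate libraries were set out before the data were examined; the other tests in this part, and the bounds against which the values were read, were chosen after the results were seen. Neither suffix class carried the differences alone, though products past 2-fold made up a larger part of suffix 2. Of the 60 products with suffix 1, 15 were at least 2-fold higher in cdk9-G57S and 6 lower, and of the 41 with suffix 2, 13 were higher and 11 lower.

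Products of 1 hairpin moved apart as far as products of different hairpins did. Counting error is argued against, since the counting interval of the difference excluded 0 in 100% of the 18 hairpins. A change in the output of the hairpin, which both products share, is argued against as the whole account, since the median difference of 1.73 log2 units lay inside the range of random pairs (0.74 to 2.09) and not below it. The median was 1.83 over 8 hairpins without products close to another hairpin's (random pairs 0.56 to 2.53). It was 1.47 over 10 hairpins with at least 1000 reads of each product (random pairs 0.56 to 2.29). Products with at least 1000 reads thus also lay apart, so few reads are not needed for a separation. However, most of these 10 hairpins held a product within 10% of another hairpin's reads. Most of the 8 hairpins in turn had a product with fewer than 1000 reads. The 2 checks therefore did not remove both doubts at once. With so few hairpins the random ranges were too wide to decide more. Reads shared only in part between hairpins need not make products close in reads, so sharing with copies was not excluded. Steps that act on each product separately stay open and were not tested. They may be strand selection (if the 2 products are opposite arms), product stability or, on the technical side, adapter ligation and size selection in the 2 preparations. Reads shared in part between hairpins, and other differences between the 2 RNA samples, stay open as well.

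The log2 ratios spread over products with an SD 30.6 times that of counting error, so counting does not account for the spread. A bias that rises or falls steadily with abundance among the listed products is argued against by a Spearman's rho of -0.0183 between mean share and log2 ratio. All of them had at least 1023 reads summed over both libraries, so rarer products were not covered. An effect of depth could not be tested with 1 library per genotype. A difference between the 2 RNA samples or library preparations other than genotype (including developmental stage, since larvae were matched by age) cannot be told apart from the mutation, because there was 1 library per genotype. The mutation itself remains a candidate explanation that was not tested against replicate error.

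Whether the typical product was higher or lower in absolute amount cannot be read from shares.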
